A study of Mus musculus with 24 samples.

How the data were processed

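Livers of Mop3fxfx mice and of Mop3fxfxCreAlb mice were collected at 6 times of 1 day, every 4 h from ZT0, at 10 and at 20 weeks of age, which gives 24 arrays with 12 per genotype and 6 per genotype and age. Each array holds pooled RNA of at least 3 mice of 1 genotype, age and time against a common reference pool. The series is a set of 2-colour Agilent arrays without dye swaps. There are no replicate arrays of the same genotype, age and time, so each time is replicated only across the 2 ages.

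The deposited scanner files come from Agilent Feature Extraction 9.1.3.1 and hold, per the file headers, the mean and background intensity of 45018 spots in each channel. They also hold, per the file headers, a log10 ratio of Cy5 over Cy3 that the authors' software had normalised. The deposited series matrix holds the same log10 ratio, with a largest difference of 0 over all arrays, so its scale, centring and direction are known, and its median was 0 on each array. Quality flags for signals above background, saturated spots and outliers are other columns of these files. Median intensity ran from 66.1 to 162.6 in Cy3 and from 83.1 to 245.8 in Cy5, between 9 and 421 spots per array were saturated in Cy3 and between 55 and 494 in Cy5.

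Mean signals were corrected for background with normexp and an offset of 50, the log ratios were normalised within each array by loess with the 1639 control spots at weight 0, and the spots of a probe were averaged. Of 41174 probes 27845 were kept, those whose Cy3 signal was well above background on at least 4 of 24 arrays. Genes were named through the transcript accession for 24375 probes, a symbol in the file for 6301 and an older symbol for 2426, from the gene table provided for the mouse, and 8072 probes kept the name in the file. The probe with the highest mean brightness stood for each gene, which left 18966 genes. No genome build comes with the arrays, so no positions are given.

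The labels state that the sample carries Cy3 and the reference Cy5. They also name a common reference for all arrays. The channels were compared within slides only, so a reference that differed between ages would not show. Within each of the 6 slides that held more than 1 array, between 80.4 and 90.9% of the probes varied more in Cy5 than in Cy3. The ratio was therefore taken as Cy5 over Cy3 and read as sample over reference, against the labels. Turning it changes the sign of every log ratio and of every difference in level, and moves every peak by 12 h. Amplitudes and their differences, each p and each count in total stay as they are. The lowest correlation between any pair of arrays was -0.25 over all probes. The filter on the Cy3 channel was kept as planned, with a filter on Cy5 as an alternative. Under the ratio used here the planned filter acts on the channel read as reference.

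The 24 arrays were fitted together with limma 3.58.1 under R 4.3.3, with the packages data.table (version 1.17.8) and statmod (version 1.5.0), to genotype x (mean, cosine and sine of 24 h) plus age. The genotype mean difference is Mop3fxfxCreAlb minus Mop3fxfx averaged over the cycle. Rhythms and their difference between genotypes were F tests of the cosine and sine terms. Amplitude is the distance from mean to peak on the log2 scale, and its standard error came from the delta method. Differences at each time came from a fit of genotype and time means plus age, and the interaction of age and genotype from the first fit with that term. Calls had an adjusted p under 0.05 by Benjamini-Hochberg over all genes of 1 test.

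The design, the alternatives, 32 gene lists with 523 members (494 measured) and the rule for naming genes were fixed before the data were examined. The direction of the ratio is an exception. It was planned as Cy3 over Cy5 and turned after the spread of the channels was seen, which also sets the genes named as highest and lowest. Named genes are Arntl, the 8 highest and 8 lowest genotype differences with 1 sign in all 12 pairs of arrays of 1 age and time, the 10 largest amplitudes in each genotype, the 10 largest differences in rhythm, and the 5 highest and 5 lowest age differences. All measured core clock and acetaminophen bioactivation genes were open to naming, and of each other list the 4 called members with the smallest p. Some genes open to naming are not reported here. The lists cover the core clock, E-box and ROR element targets, acetaminophen bioactivation, conjugation and glutathione, NRF2 targets, haem synthesis, other P450 genes, liver transcription factors, bile acid turnover, sterol synthesis, fatty acid synthesis and oxidation, glucose metabolism, heat shock, glucocorticoid and feeding response, ER stress, acute phase, cell cycle, immediate early, hepatocyte secreted and sex-biased genes. They also cover markers of macrophages, endothelium, stellate cells, cholangiocytes, lymphocytes, neutrophils, red cells, pancreas and adipose tissue. Shifts of lists were tested with camera at a preset correlation of 0.01 and with an estimated one, and rhythmic members with Fisher's exact test, two-sided.

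The arrays lie on 7 slides. At 10 weeks 3 slides hold both genotypes and 1 holds the Cre array of ZT16 alone, which has another extraction protocol. At 20 weeks 1 slide holds floxed arrays, 1 Cre arrays and 1 both. The slide was therefore tested as a block, a fixed term for genotype, rhythm and gene lists and a random one (correlation 0.222) for age and its interaction, which it would absorb, and values within the 4 slides with both genotypes are given beside the main ones.

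A fit to simulated data with seeded changes was tested first. It recovered 85 of 100 genotype differences of 0.5 and 99 of 100 of 1 with 9 false calls, 85 and 97 of 100 rhythms with 12 false calls, and 52 and 88 of 100 differences in rhythm with 5 false calls. No rhythm was called by limma in the genotype without seeded rhythms, and the median error of the peak time was 0.29 h. The simulated noise was independent between arrays and between genes, without effects of slide or collection. These rates therefore need not hold for the real arrays. Chance was tested by 100 regroupings of the arrays per result, by swapping genotypes or ages within pairs or permuting times within genotype and age.

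Alternatives were no background subtraction, the scanner's log ratio, the series matrix values, Aquantile scaling, no filter or a stricter one on dim probes, the mean of all probes of a gene, age left out, blocks for collection, slide and scan date, array weights, 6 times as a factor, each age or genotype alone, stricter thresholds and each array left out. Added after the data were seen were fits without both 20-week ZT0 arrays, with a Cy5 filter, of the 10-week arrays with a slide block, with the scan date as a block, without probes that hold a 6-base window of the telomere repeat, and for gene lists with the slide as a block, alone and with an estimated correlation. Control spots and outlier spots were left out and saturated spots kept, and the report gives no fold for a gene whose probe was saturated, in either channel, on over 6 of the 12 arrays of a group it compares, apart from 2 fitted values, of Cyp2e1 and Cyp3a11, listed as not measured with the interaction of age and genotype. At 10 weeks 140 probes were saturated in both channels on at least 10 of 12 arrays, and at 20 weeks 4.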

Results

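Liver RNA was measured on 24 Agilent 2-colour arrays, 12 from floxed control mice (Mop3fxfx) and 12 from mice that also carry Cre recombinase under the albumin promoter (Mop3fxfxCreAlb, here Cre livers). Mop3 is the older name of Arntl, also called Bmal1, a transcription factor at the centre of the circadian clock, and albumin-Cre deletes the floxed gene in hepatocytes. Livers were taken every 4 h from ZT0 (lights on) to ZT20 in mice of 10 weeks and again in mice of 20 weeks, so each genotype, age and time had 1 array. Every array carried a pool of RNA from at least 3 mice beside a common reference pool made from 10-week livers of both genotypes. No single mouse was measured, and the number of arrays limits the precision of every value. Between 56.7 and 70.3% of the probes of an array were well above background in the Cy5 channel. After the filter 18966 genes were tested, 14780 of them with a gene symbol. All changes are on the log2 scale with the standard error of the fit, over 12 arrays per genotype.

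The first question was how Arntl itself behaved in each array. In floxed livers its log2 ratio ran from -2.18 at ZT8 of the 10-week series to 1.60 at ZT0 of the 20-week series, with a fitted amplitude of 1.69 ± 0.17 and a peak at ZT 21.8. In Cre livers the ratio stayed between -0.90 and 0.52, with an amplitude of 0.22. Whether the Arntl probe lies in the floxed exon is not known here, so this signal may come from cells without deletion or from a transcript that lacks the exon. The rhythm of Arntl differed between the genotypes (limma adjusted p = 0.030), while its mean over the cycle was lower in Cre livers by a log2 difference of -0.51 ± 0.17 (adjusted p = 0.033, lower in 8 of 12 pairs of arrays of 1 age and time). Arntl was lower in Cre livers at ZT20 (-1.91 ± 0.29, adjusted p = 0.023) and higher at ZT8 (1.49 ± 0.29, adjusted p = 0.045). With the slide as a block the mean difference was -0.25 (adjusted p = 0.58). Among 42 other settings, single arrays left out included, the difference in rhythm kept its call in 22 and the mean difference in 25. These are the first signed values, and their direction opposes the labels, which give the sample Cy3 and the reference Cy5. On the arrays Cy3 was the near-constant channel and Cy5 the one that varied between times and genotypes, so every ratio here is Cy5 over Cy3, read as sample over reference. Under the dyes as labelled the sign of every log ratio and of every difference in level turns and every peak moves by 12 h. Counts of genes with a higher and with a lower level change places. Amplitudes and their differences, each p and each total count stay.

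**Figure D1:**
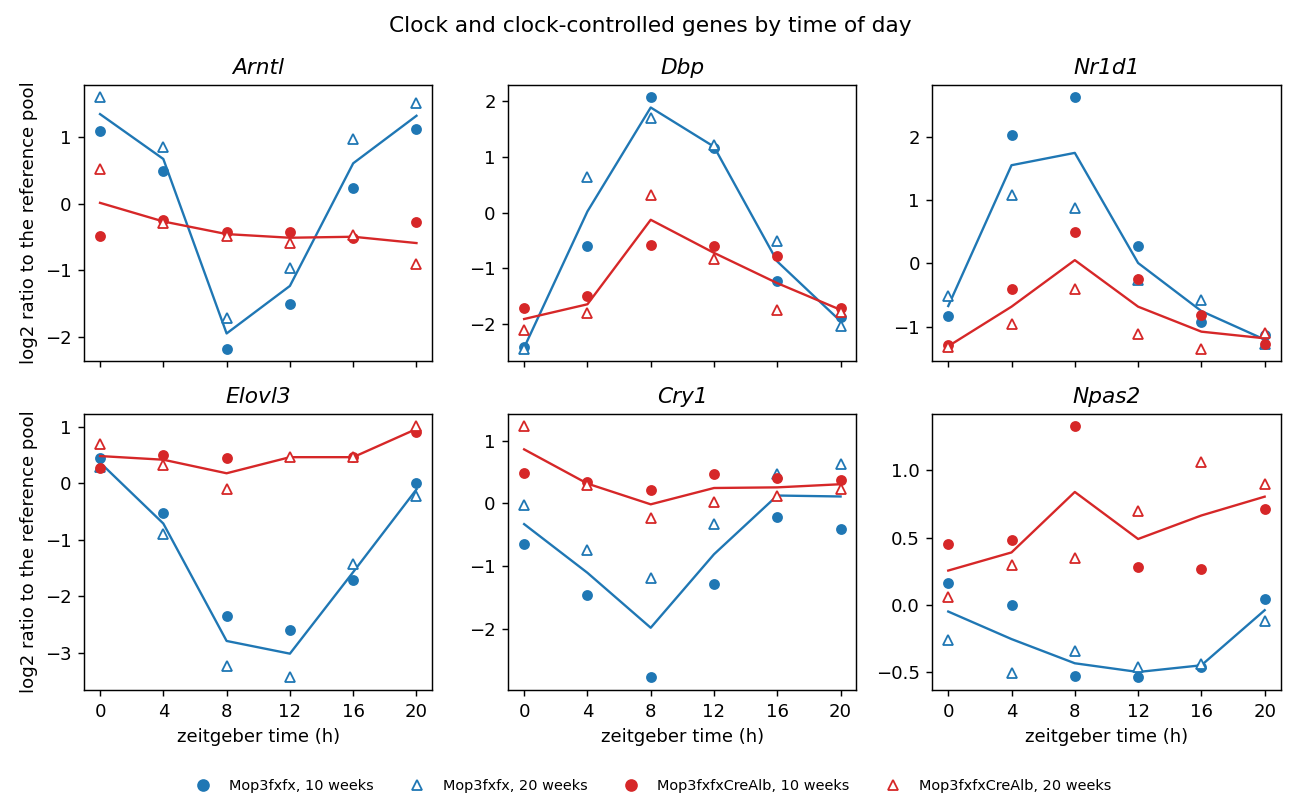
Log2 ratio of sample over reference (vertical axes) against zeitgeber time in hours (horizontal axes) for Arntl, Dbp, Nr1d1, Elovl3, Cry1 and Npas2, with 1 point per array, blue for floxed and red for Cre livers, filled circles for 10 weeks and open triangles for 20 weeks, and lines through the mean of both ages at each time. Arntl spans -2.18 to 1.60 in floxed livers and -0.90 to 0.52 in Cre livers.

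The main comparison asked which genes differed in level over the whole cycle between Cre and floxed livers. No group carried albumin-Cre without the floxed gene, so an effect of Cre itself cannot be told apart from loss of Arntl. Ntrk2, a neurotrophin receptor, rose most among the named genes, by 4.62 ± 0.23, followed by Lpl, which hydrolyses the triglycerides of lipoproteins (3.81 ± 0.20), the cytochrome P450 Cyp2c55 (2.80 ± 0.18) and Grk5, a kinase of G protein-coupled receptors (2.72 ± 0.11). Ndrg1, a gene induced by hypoxia and stress (2.44 ± 0.13), Hebp2 (2.21 ± 0.13), the glutathione transferase Gstm2 (2.15 ± 0.14) and Ccn4, a secreted matricellular protein (2.13 ± 0.10), rose as well. Cfd, the complement factor adipsin, fell most (-3.05 ± 0.36), with Nat8, an N-acetyltransferase (-2.97 ± 0.25), the lipid droplet protein Cidec (-2.26 ± 0.26) and the fatty aldehyde dehydrogenase Aldh3a2 (-2.25 ± 0.18). Aatk (-2.11 ± 0.17), the thyroid hormone deiodinase Dio1 (-2.05 ± 0.22), Cyp2a4 (-1.91 ± 0.22) and Clstn3 (-1.86 ± 0.17) fell too. These 16 genes were chosen among those that changed in 1 direction in all 12 pairs, so that agreement is no separate evidence, and their limma adjusted p ran from 1.9e-12 for Grk5 to 6.7e-06 for Cfd. Across the 3 Ntrk2 probes the difference ran from 0.02 to 4.62, the size given being that of the brightest probe. Cyp2a4 was saturated in Cy5 on 5 of 12 floxed arrays, which can shrink its difference. Of the 4 slides that held both genotypes, the first was compared at ZT0 alone, and the last, at 20 weeks, sets Cre arrays of ZT0 and ZT4 against floxed arrays of ZT16 and ZT20, so its values mix genotype with time. Within these slides Ntrk2 differed by 4.30, 4.70, 4.94 and 5.80 and Nat8 by -3.73, -3.37, -3.75 and -3.37.

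In total 4554 of 18966 genes differed, 2267 higher and 2287 lower in Cre livers (6862 at unadjusted p under 0.05). Of these, 1138 (25.0%) had 1 sign in all 12 pairs, a share that the call on the same pairs favours. The 10-week arrays alone gave 645 genes and the 20-week arrays 5810. Of the 645, 579 (89.8%) had the sign of the 10-week difference at 20 weeks and of the 5810, 4237 (72.9%) had at 10 weeks the sign of the 20-week difference, where 59.9% of all genes had 1 sign at both ages. Called at both ages in 1 direction were 210 higher and 207 lower genes, with 48.1 and 49.4 expected if the calls of the ages were unrelated. The 20-week genotypes lay mostly on different slides, and with the slide as a block 1840 genes were called, with the scan date as a block 2040 and with array weights 7209. Across all genes the difference within a slide correlated with that of the other age at r = 0.40, 0.41 and 0.40 for the 3 slides of 10 weeks and 0.53 for the 20-week one, where genes are not independent replicates.

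**Figure D2:**
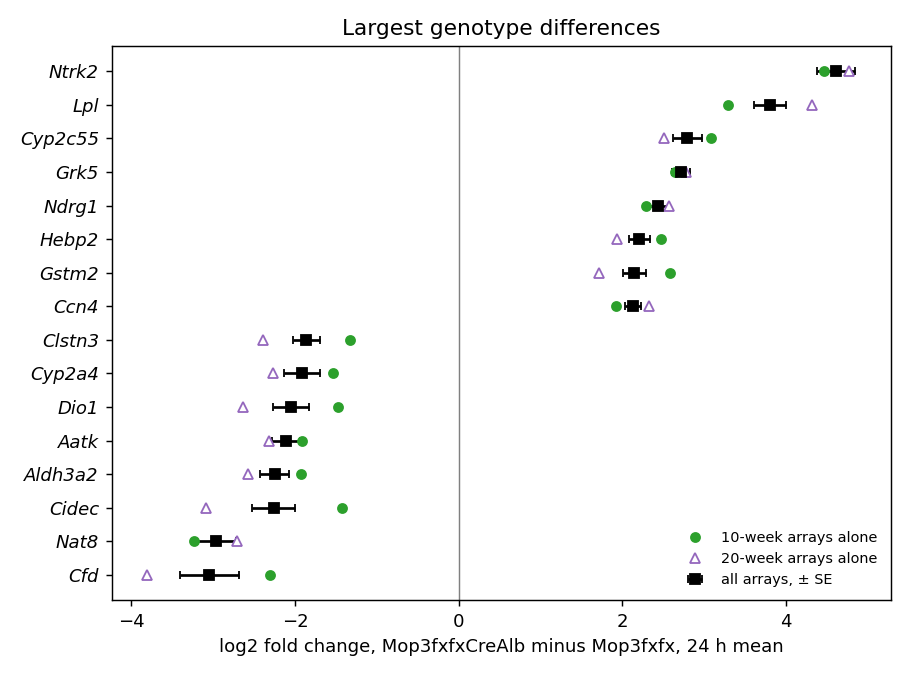
Log2 difference, Cre minus floxed livers averaged over 24 h (horizontal axis), for the 16 named genes (vertical axis), with black squares and SE bars for all arrays, green circles for the 10-week arrays alone and open triangles for the 20-week arrays alone. Ntrk2 has 4.47 at 10 and 4.77 at 20 weeks, and Nat8 has -3.23 and -2.71.

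Clock genes were grouped by the element known to drive them, and no test compared the groups with each other. Of 14 targets of the E-box, the DNA element that ARNTL binds, 8 fell and none rose, with a median of -0.41. Among them Nr1d2 (-1.59 ± 0.20) and Nr1d1 (-0.93 ± 0.18), which encode the REV-ERB repressors, fell together with Ciart (-1.16 ± 0.21), a repressor of the clock, and the transcription factor Dbp (-0.88 ± 0.18). The 3 Nr1d1 probes ran from -0.93 to 0.00. Of 8 targets of the ROR element, which REV-ERB proteins repress, 5 rose and 1, Arntl itself, fell, with a median of 0.75. These included Elovl3, an enzyme of fatty acid elongation (1.80 ± 0.12, saturated in Cy5 on 5 of 12 Cre arrays), the ARNTL partner Npas2 (0.86 ± 0.12) and the repressor Cry1 (0.99 ± 0.17). Camera gave adjusted p = 0.0045 for the E-box list and 0.00046 for the ROR list, and with an estimated correlation adjusted p = 0.40 and adjusted p = 0.10. Of 22 core clock genes 3 rose and 6 fell, with a median of -0.04 (camera adjusted p = 0.85). Adjusted over the list alone, 8 E-box targets, 7 ROR targets and 10 core clock genes passed. With the slide as a block the E-box median was -0.32 and the ROR median 0.57, and within the 4 slides the E-box list had 0.07, -0.28, -0.31 and -0.52 and the ROR list 0.25, 0.54, 0.79 and 0.20, values that for these rhythmic genes depend on the times each slide holds.

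The series concerns the activation of acetaminophen, which cytochrome P450 enzymes turn into a reactive metabolite. Of 10 genes of acetaminophen bioactivation 4 were called lower in Cre livers and none higher. Por, the reductase that passes electrons to every microsomal P450, fell by 0.86 ± 0.14 and was lower in all 12 pairs (adjusted p = 0.00017), with Cy5 saturated on 6 of 12 floxed arrays and no Cre array. Cyp3a13 had -0.80 ± 0.16 (adjusted p = 0.0011), lower in 11 of 12 pairs. Cyp2a5 fell too (adjusted p = 0.00019, lower in 11 of 12 pairs), and no fold is given, as Cy5 was saturated on 11 of 12 floxed arrays and no Cre array. Cyp2e1, the main enzyme of this activation at toxic doses, was called lower (limma adjusted p = 0.0093, lower in 11 of 12 pairs), with the limit of saturation given below. Cyp1a2 (0.00, on a probe with part of the telomere repeat), Cyp3a25 (0.07), Cyb5b (-0.16) and Cyb5r3 (-0.30) did not pass, and neither did Cyb5a, saturated in Cy5 on all 12 floxed arrays, or Cyp3a11, saturated in Cy5 on all 24 arrays, for which no fold is given. The list had a median of -0.23 and did not pass camera (adjusted p = 0.071, adjusted p = 0.47 with an estimated correlation). It passed with the slide as a block (adjusted p = 0.015, adjusted p = 0.28 with an estimated correlation), as it did without the filter on dim probes (adjusted p = 0.036). Adjusted over the list alone 5 of the 10 passed. Cyp2e1 was saturated in Cy5 on 11 of 12 arrays at 10 weeks and on 5 of 12 at 20 weeks, so its size is not measured. In Cy3 it was saturated on 10 of 12 arrays at 10 weeks. The signs of its 10-week pairs therefore compare clipped signals and are no evidence of a fall. By genotype its Cy5 was saturated on 10 of 12 floxed and 6 of 12 Cre arrays. With the slide as a block Cyp2e1 did not pass (adjusted p = 0.30), while Por kept -0.78 (adjusted p = 0.012) and Cyp3a13 -0.65 (adjusted p = 0.034), and Cyp2a5 passed again (adjusted p = 0.0019). Within the 4 slides that held both genotypes Por had -0.02, -0.72, -0.81 and -1.39, and the list median was -0.41, -0.09, -0.06 and -0.71.

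**Figure D3:**
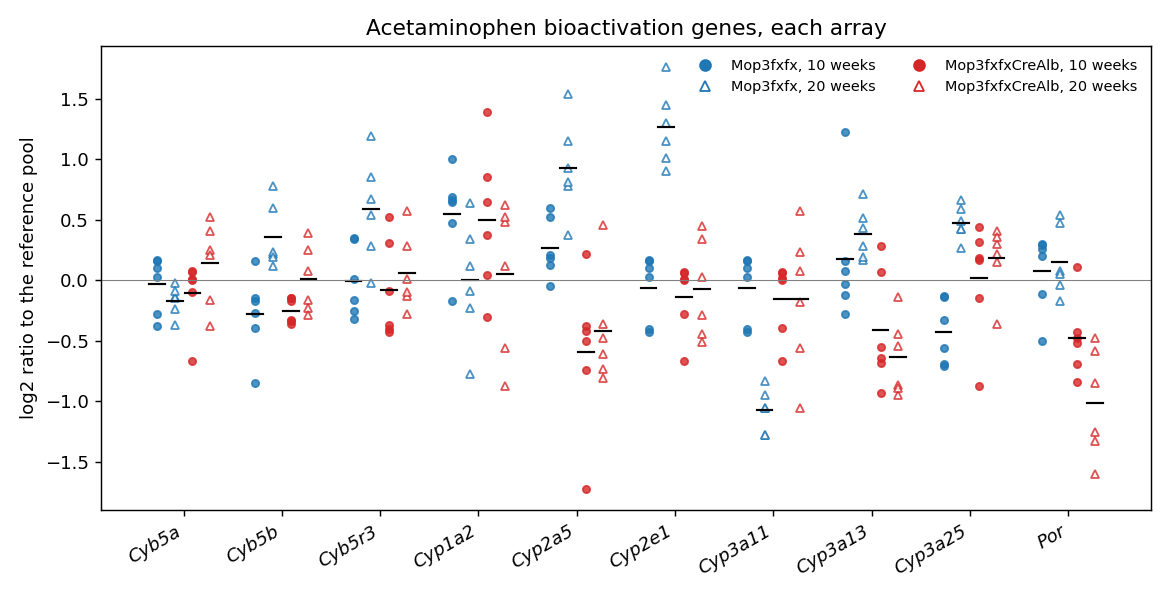
Log2 ratio of sample over reference of each array (vertical axis) for the 10 genes of acetaminophen bioactivation (horizontal axis), blue for floxed and red for Cre livers, filled circles for 10 weeks and open triangles for 20 weeks, with a black bar at the mean of each group of 6 arrays. Cyp2e1 separates at 20 weeks and not at 10 weeks, where it is saturated in Cy5 on 11 of 12 arrays, and Cyp3a11 is saturated on all 24 arrays.

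Genes that conjugate or detoxify metabolites moved both ways. Of 33 genes of conjugation and glutathione 6 rose and 13 fell (20 adjusted over the list alone, median -0.12). Besides Gstm2, Gstm6 rose (1.21 ± 0.12), while the glutathione transferase Gstt2 (-1.29 ± 0.11) and the phenol sulfotransferase Sult1a1 (-1.59 ± 0.16) fell in all 12 pairs. Of 15 targets of NRF2, the regulator of the antioxidant response, 3 rose and 4 fell (8 over the list alone), among them Gsta2 (-1.07 ± 0.19) and Gclm, a subunit of the enzyme that starts glutathione synthesis (-0.64 ± 0.13). Of 8 genes of haem synthesis Uros rose (0.17 ± 0.06) and 3 fell (6 over the list alone), including Cpox (-0.55 ± 0.13). Of 32 other P450 genes 5 rose and 7 fell (12 over the list alone), Cyp2c40 by 0.52 ± 0.08 and Cyp2c38 by -0.74 ± 0.13. Of 21 xenobiotic and liver transcription factors 2 rose and 8 fell (11 over the list alone). Among these Stat5b rose (0.39 ± 0.06), and the fatty acid receptor Ppara (-0.80 ± 0.15), the hepatocyte regulator Hnf4a (-0.41 ± 0.08) and the xenobiotic receptor Nr1i2 (-0.55 ± 0.10) fell. Other probes differed, from 0.10 to 0.39 for Stat5b and from -0.41 to 0.07 for Hnf4a, whose probes disagree in sign. None of these 5 lists passed camera (lowest adjusted p = 0.071). The conjugation list (adjusted p = 0.0062) and the transcription factors (adjusted p = 0.0077) passed as lower with the slide as a block, and with an estimated correlation besides they had adjusted p = 0.38 and adjusted p = 0.065. Both also passed without the filter on dim probes (adjusted p = 0.036 and adjusted p = 0.033), and the transcription factors without both 20-week ZT0 arrays (adjusted p = 0.041).

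The sterol synthesis, fatty acid oxidation and fatty acid synthesis lists passed camera at the preset correlation, but not with an estimated one. Of 22 sterol synthesis genes 16 rose and 1 fell, with a median of 0.56 (camera adjusted p = 6.4e-07, 18 adjusted over the list alone). Insig2, which retains the sterol sensor in the endoplasmic reticulum (1.14 ± 0.11), and the enzymes Msmo1 (0.88 ± 0.16), Idi1 (0.81 ± 0.14) and Fdps (0.65 ± 0.13) rose. Of 25 fatty acid oxidation genes 16 fell and 1 rose, with a median of -0.37 (camera adjusted p = 6.4e-07, 18 over the list alone). The thioesterase Acot4 (-1.21 ± 0.15), the pantetheinase Vnn1 (-1.21 ± 0.17) and the peroxisomal thiolase Acaa1b fell in all 12 pairs (the second Acot4 probe had -0.54, and Acaa1b, saturated in Cy5 on 9 of 12 floxed arrays, has no fold here), and the 1 that rose was Pdk4, a kinase that shuts pyruvate dehydrogenase (1.5 ± 0.20). Of 19 fatty acid synthesis genes 8 fell and 2 rose, with a median of -0.35 (camera adjusted p = 0.045, 11 over the list alone), with Me1 (-0.84 ± 0.14), Fads2 (-0.68 ± 0.12) and Mlxipl (-0.62 ± 0.10) lower. With an estimated correlation these lists had adjusted p = 0.38, adjusted p = 0.12 and adjusted p = 0.62 in this order, so none of the 5 lists past camera held, and with collections as blocks fatty acid synthesis had adjusted p = 0.089. Within the 4 slides with both genotypes the sterol median was 0.51, 0.58, 0.45 and 0.31, that of oxidation -0.33, -0.38, -0.45 and -0.61 and that of fatty acid synthesis -0.39, -0.25, -0.19 and -0.08. Of 16 genes of bile acid and cholesterol turnover 2 rose and 3 fell (5 over the list alone), with Akr1d1 lower (-0.79 ± 0.16) and Abcb11, the bile salt export pump, higher (no fold given, as Cy5 was saturated on 7 of 12 Cre arrays, camera adjusted p = 0.87 for the list).

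Among other liver programmes, 2 of 19 glucose genes rose and 4 fell (6 adjusted over the list alone). The glucose transporter Slc2a2 (-0.88 ± 0.10, second probe -0.56) and the glycogen synthase Gys2 (-0.51 ± 0.08) fell and the glucokinase regulator Gckr rose (0.70 ± 0.10, saturated in Cy5 on 6 of 12 Cre arrays). Of 15 heat shock and temperature genes 1 rose and 2 fell (3 over the list alone), with Hspb1 at -1.61 ± 0.21 and Cirbp at 0.55 ± 0.17. Of 15 genes that respond to glucocorticoids or feeding 5 rose and 1 fell (6 over the list alone), Tsc22d3 by 0.74 ± 0.18 (0.42 to 0.87 over 3 probes) and Ddit4 by 0.84 ± 0.23. Of 21 genes of ER stress and amino acid response 5 fell and none rose (7 over the list alone), with the asparagine synthetase Asns at -1.59 ± 0.26 and the pseudokinase Trib3 at -1.46 ± 0.16, where the second Trib3 probe had -0.26. Of 22 acute phase and complement genes 1 rose and 4 fell (5 over the list alone), including Saa4 (-0.75 ± 0.19, second probe -1.27). Of 19 cell cycle genes 5 rose and 4 fell (10 over the list alone), and the replication genes Mcm6 (1.35 ± 0.16) and Mcm2 (0.51 ± 0.08) and the cell cycle inhibitor Cdkn1a (1.34 ± 0.18) were higher. Of 12 immediate early genes 2 rose and 2 fell (4 over the list alone), and none of 11 genes secreted by hepatocytes passed limma, over all genes or over the list alone, where 10 of the 11 were saturated in Cy5 on at least 6 of the 12 arrays of an age. None of these lists passed camera (adjusted p from 0.094 to 0.66). Under the slide block ER stress (adjusted p = 0.00025), acute phase (adjusted p = 0.002), hepatocyte secreted (adjusted p = 0.013, with the direction turned from higher to lower) and heat shock genes (adjusted p = 0.045) passed as lower, and with an estimated correlation besides they had adjusted p = 0.12, adjusted p = 0.38, adjusted p = 0.38 and adjusted p = 0.33.

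Markers of other cell types gave few calls. Of the marker lists, 1 of 14 macrophage genes rose (Mpeg1, 0.46 ± 0.12, second probe 0.19), as did 2 of 12 sinusoidal endothelial genes, 4 of 12 stellate cell and fibroblast genes and 2 of 9 cholangiocyte genes, and none of these fell. The cholangiocyte pair was Spp1 (1.39 ± 0.17) and Sox9 (1.06 ± 0.12, with 0.07 to 1.11 over 3 probes), and the stellate group included Lum (0.59 ± 0.15). Lrat and Pdgfrb, also among the stellate genes that rose, are on probes with part of the telomere repeat described with the ages below. What the repeat adds to the stellate result was not tested. None of 13 lymphocyte or 5 neutrophil genes passed limma, and 1 of 5 red cell genes, Alas2, fell (-0.56 ± 0.07). Of 9 pancreas genes Amy2 rose (0.72 ± 0.23), which includes a single Cre array on which the pancreas genes stood high. Over 42 other settings the Amy2 difference ran from 0.31 to 1.14 and lost its call in 9. Of 7 adipose genes 1 rose (Fabp4, 0.50 ± 0.11, with probes that disagree in sign, from -0.06 to 0.50) and 3 fell (Cfd, Cidec and Car3). Among 16 male-biased liver genes 5 rose and 1 fell, with Serpina12 higher (1.41 ± 0.14), and among 13 female-biased ones 2 fell, Cyp2a4 and Acot3 (-1.28 ± 0.19). Adjusted over the list alone the counts were 1 for macrophage, 2 for endothelial, 4 for stellate, 2 for cholangiocyte, 0 for lymphocyte, 0 for neutrophil, 1 for red cell, 1 for pancreas, 4 for adipose, 6 for male-biased and 2 for female-biased genes. None of these lists passed camera (adjusted p from 0.071 to 0.95), and the median, mean and camera direction differed in sign for the macrophage, endothelial and lymphocyte lists. The stellate list passed as higher under the slide block (adjusted p = 0.0062) and the adipose list as lower (adjusted p = 0.013), with adjusted p = 0.28 and adjusted p = 0.27 under an estimated correlation besides. The male-biased list passed as higher with collections as blocks (adjusted p = 0.015) and without the filter on dim probes (adjusted p = 0.033), but had adjusted p = 0.51 with an estimated correlation and adjusted p = 0.87 with the slide as a block.

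The next question was which transcripts followed a 24 h rhythm in floxed livers. Rgs16, a regulator of G protein signalling, had the largest amplitude, 2.65 ± 0.25 with a peak at ZT 8.6, followed by Dbp (2.18 ± 0.18, ZT 9.4), Ciart (1.86 ± 0.21, ZT 11.2) and Elovl3 (1.80 ± 0.11, ZT 22.9). Nr1d2 (1.71 ± 0.20, ZT 9.7), Nr1d1 (1.55 ± 0.18, ZT 6.8), the deubiquitinase Usp2 (1.59 ± 0.21, ZT 12.6), Lpin1, a phosphatidate phosphatase (1.52 ± 0.21, ZT 11), and the extracellular matrix protein Spon2 (1.46 ± 0.11, ZT 0.3) followed. Nr1d1 had 0.58 as the mean of its probes and 2.22 with the scanner's log ratio, and Ciart 3.01 with the latter. The limma adjusted p of these 9 genes ran from 1.6e-07 for Elovl3 to 0.0014 for Lpin1. Altogether 290 genes were rhythmic (2237 at unadjusted p under 0.05), 30 of them with an amplitude of at least 1. Their peaks gathered around lights on, with 84 genes between ZT20 and ZT24 and 62 between ZT0 and ZT4, and around ZT8 to ZT12, with 65. Of 290 genes chosen on the floxed arrays of 10 weeks alone, 85.2% had peaks at both ages within 4 h of each other, and of 290 chosen at 20 weeks alone 83.1%, against 40.4% of all genes. The count fell to 173 without floxed replicate 10 (ZT12 at 20 weeks), to 154 with age left out and to 76 with 6 times as a factor, and rose to 453 with the slide as a block, 495 with array weights and 651 with the scan date as a block.

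Among the rhythmic genes the clock lists were the most enriched. Of 22 core clock genes 13 were rhythmic in floxed livers (Fisher's exact test, two-sided, adjusted p = 2.7e-17, 15 adjusted over the list alone), including Per1 (0.98 ± 0.17, ZT 12.4), Per2 (0.91 ± 0.14, ZT 13.2), Cry1 (1.01 ± 0.17, ZT 19.2) and Clock (0.54 ± 0.09, ZT 21.9). As the mean of its probes Per2 had 0.18 and was not called (adjusted p = 0.85). Of 14 E-box targets 10 were rhythmic (adjusted p = 9.1e-15, 12 over the list alone) and of 8 ROR targets 6 (adjusted p = 3.5e-09, 6 over the list alone), with Dbp at ZT 9.4 and Arntl at ZT 21.8. Of 15 glucocorticoid and feeding genes 4 were rhythmic (adjusted p = 0.00041, 6 over the list alone), Lpin1, Fkbp5, a co-chaperone of the glucocorticoid receptor (1.27 ± 0.26), and the clock genes Per1 and Per2, with peaks between ZT 11 and ZT 13.2. Outside the clock lists 2 of 13 were rhythmic (unadjusted p = 0.015). Of 19 cell cycle genes 5 were rhythmic (adjusted p = 6.3e-05, 5 over the list alone), including Cdkn1a (1.39 ± 0.18, ZT 20.7) and Wee1, a kinase that holds back mitosis (0.57 ± 0.11, ZT 11.8), and 4 of 18 outside the clock lists (unadjusted p = 0.00011). These 4 include Rrm2, whose probe holds part of the telomere repeat described with the ages below. No acetaminophen bioactivation gene was rhythmic by limma (1 over the list alone), and Por, with a peak at ZT 13.4, had an amplitude of 0.35 ± 0.14 (adjusted p = 0.44). Of the glucose genes Gys2 (0.52 ± 0.08, ZT 12.1) and Slc37a4 (0.41 ± 0.08, ZT 12.8) were rhythmic and 7 over the list alone. Of the other P450 genes 2 were rhythmic (2 over the list alone), including Cyp2g1 (0.72 ± 0.14, ZT 7.5).

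Single members were rhythmic in 9 further lists, each without enrichment (lowest Fisher adjusted p = 0.52). They were Gclc in both the conjugation and the NRF2 list, Stat5b among the transcription factors, Abcb11 in the bile acid list, Insig2 in the sterol list, Elovl3 in the fatty acid synthesis and male-biased lists, Trib3 in the ER stress list and Sox9 in the cholangiocyte list. Insig2 had an amplitude of 0.89 ± 0.11 with a peak at ZT 22.6, Trib3 0.92 ± 0.16 at ZT 6.7 and Sox9 0.69 ± 0.12 at ZT 22.1. Adjusted over the list alone the counts were 1 for conjugation, 2 for NRF2, 1 for haem, 1 for transcription factors, 4 for bile acid, 4 for sterol, 3 for fatty acid synthesis, 4 for fatty acid oxidation, 2 for ER stress, 1 for stellate, 2 for cholangiocyte, 4 for male-biased and 3 for female-biased genes. The heat shock, acute phase, immediate early, hepatocyte secreted, macrophage, endothelial, lymphocyte, neutrophil, red cell, pancreas and adipose lists had 0 by limma on both counts.

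In Cre livers the question was which rhythms were measured without the hepatocyte clock gene, and which differed. Lpin1 (1.18, peak at ZT 11.9), Nr1d2 (1.11, ZT 10.6), Dbp (0.81, ZT 10.3) and Per1 (0.78, ZT 12.1) had the larger amplitudes among the genes named above, with unadjusted p of 1e-04, 0.00011, 0.00094 and 0.00085. None passed after adjustment, and limma called 0 rhythmic genes in Cre livers (1708 at unadjusted p under 0.05). Of the 290 genes rhythmic in floxed livers 282 (97.2%) had the smaller amplitude in Cre livers, with medians of 0.51 and 0.21. The choice of these genes on the floxed arrays favours that share. Among genes chosen on the floxed arrays of 10 or of 20 weeks, 64.8 and 81.7% had the smaller amplitude in Cre livers at the other age. Of the 290 genes called over all arrays 128 (44.1%) had an unadjusted p under 0.05 in Cre livers, against 9.0% of all genes. Adjusted over the list alone, 3 core clock, 4 E-box, 2 fatty acid oxidation, 1 glucose, 2 glucocorticoid and feeding and 1 cell cycle gene were rhythmic in Cre livers. Leaving out Cre replicate 5 (10 weeks, ZT16), the array on a slide of its own with another extraction protocol, gave 28 rhythmic genes, leaving out floxed replicate 7 (20 weeks, ZT0) gave 12, Cre replicate 12 (20 weeks, ZT20) 8, and Cre replicate 6 or 9 gave 1 each. Array weights gave 108 and the scan date as a block 11.

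The difference in rhythm was itself tested and was called for 6 genes, all with the smaller amplitude in Cre livers (543 at unadjusted p under 0.05). Elovl3 went from 1.80 in floxed to 0.27 in Cre livers (adjusted p = 0.00086), Spon2 from 1.46 to 0.47 (adjusted p = 0.018) and Arntl from 1.69 to 0.22. The saturation of Elovl3 on 5 Cre arrays can flatten its rhythm there. A630005I04Rik went from 0.87 to 0.06 (adjusted p = 0.0013), the DNA methyltransferase Dnmt3b from 0.70 to 0.09 (adjusted p = 0.047), and Lgalsl from 1.11 to 0.16 (adjusted p = 0.016). The Lgalsl probe holds part of the telomere repeat described with the ages below, and without such probes 4 genes were called, with Dnmt3b at adjusted p = 0.051. Among other settings Dnmt3b kept its call in 8 of 42, Arntl in 22 of 42, Lgalsl in 31 of 41, Spon2 in 33 of 42, Elovl3 in 37 of 41 and A630005I04Rik in 38 of 42. In floxed livers all 6 peaked between ZT 21.0 and ZT 0.3. For 156 of the 290 rhythmic genes (53.8%) the difference had an unadjusted p under 0.05. Of 8 ROR targets 2 were called, Elovl3 and Arntl (Fisher adjusted p = 7.5e-05). Arntl is the floxed gene itself, so this enrichment counts the gene that the genotype targets. Adjusted over the list alone 6 ROR targets, 10 core clock genes, 8 E-box targets and 1 gene each of the sterol, fatty acid synthesis, cell cycle and male-biased lists passed. Dbp, with 2.18 against 0.81, had adjusted p = 0.14. The count fell to 2 without floxed replicate 4 or without Cre replicate 4 or 10 (all ZT12), to 3 without floxed replicate 9 (ZT8), and rose to 10 without Cre replicate 9 (ZT8). It was 0 with 6 times as a factor and 0 by limma at each age alone, 2 without both 20-week ZT0 arrays, 10 with slides or with collections as blocks and 11 with the scanner's log ratio.

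Taken time by time, the order of the times depended on the threshold. Limma called 22 genes at ZT0, 26 at ZT4, 74 at ZT8, 100 at ZT12, 78 at ZT16 and 23 at ZT20, and 178 genes at any of the times. At unadjusted p under 0.05 there were 1724, 1289, 1238, 1812, 2499 and 1530 from ZT0 to ZT20, so ZT8 had the fewest, and with array weights 362 genes were called at ZT4 against 86 at ZT8. More of the called genes were higher than lower in Cre livers at each time, with 53 against 21 at ZT8, 59 against 41 at ZT12 and 68 against 10 at ZT16. At ZT12 this turned without background subtraction (83 against 96), with the scanner's log ratio (60 against 64), with the mean of all probes (69 against 78), with array weights (286 against 333) and without Cre replicate 5 or 11 (79 against 82). At ZT4 it turned with array weights (149 against 213), with the scan date as a block (42 against 45) and without floxed replicate 2 (9 against 10), and at ZT0 without floxed replicate 1 (126 against 921). Elovl3 was higher in Cre livers at ZT8 (2.97 ± 0.28), ZT12 (3.58 ± 0.35) and ZT16 (2.03 ± 0.28), and Spon2 by 2.41 ± 0.30, 2.92 ± 0.30 and 2.10 ± 0.30 at these times. Cdkn1a was higher at ZT8 (2.67 ± 0.40) and ZT12 (2.65 ± 0.40). Rgs16 was lower at ZT8 and at ZT12 (-3.54 ± 0.70 each), Ciart at ZT12 (-2.60 ± 0.50), Dbp at ZT8 (-2.02 ± 0.40) and Nr1d1 at ZT4 (-2.23 ± 0.40). Ntrk2, Grk5, Ndrg1, Hebp2 and Ccn4 were called at all 6 times. Each time had 2 arrays per genotype with the spread pooled over all cells, so single arrays set these counts, as when 1047 genes were called at ZT0 without floxed replicate 1 and 5 without floxed replicate 7. With the slide as a block the 10-week Cre array of ZT16, alone on its slide, is absorbed by its slide term. That leaves 1 Cre array at ZT16, so no count is given there.

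The comparison of ages set the 20-week against the 10-week collection. Among the genes that fell were the serum amyloids Saa3, Saa2 and Saa1 and Fgl1 (-1.5 ± 0.29) and Lrg1, also secreted by the liver in inflammation, chosen as the lowest fitted values. No fold is given for Saa1, Saa2 and Lrg1, saturated at 10 weeks in Cy5 on 9, 8 and 11 of 12 arrays, or for Saa3, saturated there in Cy3 on 8 of 12, and their order is not measured. Cy3, read as the reference, was also saturated for Saa1 on 9 arrays at 10 weeks and 11 at 20 weeks, and for Saa2 on 10 and 11. Whether the reference RNA was alike at both ages was not tested, and a difference in it would enter every age difference. Of the 22 acute phase and complement genes 13 fell and 1 rose, with a median of -0.73. Serpina3n (-1.12 ± 0.20) was among those that fell. Of the 22 members 9 were saturated in Cy5 on at least 6 of the 12 arrays of an age. Lcn2, another member, stood highest on 1 10-week array, the floxed one of ZT16 (2.58 against 1.15 on the next highest array). What that array adds to the fall of the list was not tested. The limma adjusted p of the 5 lowest genes named first ran from 5.4e-07 for Lrg1 to 0.0075 for Saa3. The 5 largest rises, in Syt6 (2.58 ± 0.31), Dnajb8 (2.53 ± 0.31), Eml6 (2.52 ± 0.31), Adamts4 (2.43 ± 0.30) and Adamtsl3 (2.39 ± 0.32), were all on probes that hold part of the telomere repeat CCCTAA. Over 37 other settings Eml6 ran down to 0.15 and lost its call in 1. Among genes whose probe lacks the repeat, named after their values were seen, the P450 genes Cyp2b9 (2.34 ± 0.41) and Cyp2b13 (2.11 ± 0.32) rose most together with Plaat5 (2.15 ± 0.29) and Lrtm1 (2.11 ± 0.22). Scd1, the stearoyl-CoA desaturase (no fold given, as Cy5 was saturated on 8 of 12 arrays at 20 weeks), Elovl6 (1.21, on a repeat probe), Cyp2b10 (1.47), Gstt3 (1.10, on a repeat probe), Gsta2 (1.03) and Nfe2l2 (0.98), which encodes NRF2, rose too. Limma called 5949 genes, 3422 higher and 2527 lower at 20 weeks (8088 at unadjusted p under 0.05). Age lies across slides and collection days, and with the slide as a random block 2018 genes were called and with the scan date 737. Under the scanner's own log ratios the balance turned, with 3127 higher and 3431 lower.

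**Figure D4:**
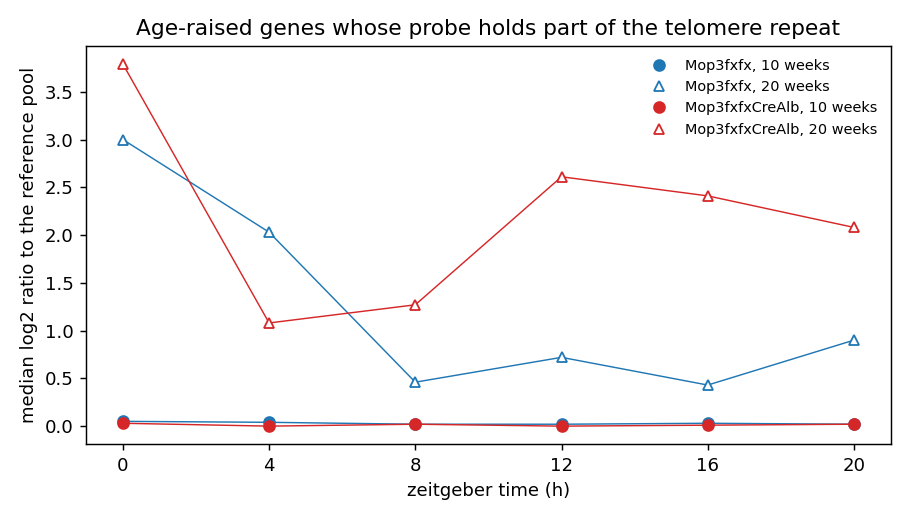
Median log2 ratio of sample over reference (vertical axis) against zeitgeber time in hours (horizontal axis) over the 157 genes at least 2-fold higher at 20 weeks whose probes hold a 6-base window of the telomere repeat, with 1 point per array, blue for floxed and red for Cre livers, filled circles for 10 weeks and open triangles for 20 weeks, joined by lines. The 10-week arrays lie between 0.00 and 0.05 and the 20-week arrays between 0.43 and 3.79.

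By list, 15 of the 33 conjugation genes were higher (raised) and 3 lower (lowered) in the 20-week collection, whatever the cause, as were 6 and 1 of the NRF2 targets, 14 and 8 of the other P450 genes, and 3 and 1 of the 10 acetaminophen bioactivation genes, 4 of which were saturated in Cy5 on at least 6 of the 12 arrays of an age. Of 19 fatty acid synthesis genes 8 were raised and 0 lowered by limma, and of 25 oxidation genes 11 and 3, such as Elovl5 (0.97) and Ehhadh (0.77). Of 22 sterol synthesis genes 2 were raised and 8 lowered, such as Mvk (-0.88). Of 12 stellate and fibroblast markers 1 was raised and 6 were lowered, of 12 endothelial markers 1 and 6 and of 14 macrophage markers 0 and 5, as with Col1a1 (-1.06), Lyve1 (-0.99) and C1qc (-0.59). Of 13 lymphocyte markers 7 were raised and 0 lowered, as with Cd3g (0.96). Genes of ER stress (0 raised, 8 lowered), immediate early genes (0 and 3), hepatocyte secreted genes (1 and 5), male-biased genes (2 and 8) and transcription factors (4 and 6) had more lowered than raised. The haem (3 and 1), female-biased (5 and 1), adipose (2 and 1), pancreas (1 and 0) and red cell lists (1 and 0) had more raised than lowered, and cholangiocyte (0 and 2), heat shock (1 and 2) and glucose genes (2 and 4) more lowered. Core clock (3 and 2), E-box (1 and 1), ROR (1 and 1), bile acid (3 and 3), glucocorticoid (3 and 3), cell cycle (1 and 1) and neutrophil genes (0 and 0) differed by 1 at most. These counts are members past limma over all genes, raised first, with no test of the list.

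Whether the genotype difference changed with age was tested by an interaction term, called for 2019 genes, 647 with a more positive and 1372 with a more negative difference at 20 weeks (5244 at unadjusted p under 0.05). Lpl was higher in Cre livers by 3.29 at 10 and 4.32 at 20 weeks (adjusted p = 0.047), while Gstm2 went from 2.59 to 1.72 (adjusted p = 0.019) and Cry1 from 1.51 to 0.47 (adjusted p = 0.017). Cidec went from -1.42 to -3.09 (adjusted p = 0.013), Dio1 from -1.47 to -2.63 (adjusted p = 0.049) and Clstn3 from -1.33 to -2.39 (adjusted p = 0.017). Cyp3a25 had 0.44 and -0.29 (adjusted p = 0.046). Blocks moved this count to 812 (slide), 147 (scan date) and 4201 (collections), leaving out both 20-week ZT0 arrays gave 5238, and at an adjusted p under 0.01 there were 12, while single arrays moved the count between 968 without floxed replicate 4 and 4335 without Cre replicate 7. Across genes the genotype differences of the 2 ages correlated with r = 0.49, where genes are not independent replicates.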

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

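The chance tests of the model counts were planned, and the tests of the telomere repeat, of both 20-week ZT0 arrays, of the choice of rhythmic genes and of both channel explanations were chosen after the result was seen.

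Among 100 regroupings of the arrays, 1 (the real one) gave as many genes with a genotype mean difference (4554, highest other 1081). The same held for rhythmic genes in floxed livers, with 1 of 100 (290, highest other 17). It also held for the age difference, with 1 of 100 (5949, highest other 4497). A share of 1 of 100 is the lowest this test can give. For Cre livers this is no test, since any regrouping gives at least 0. There limma called 0 rhythmic genes (1708 at unadjusted p under 0.05, highest other split 42). No slide held both ages, and some slides held a single genotype, so swapping labels also breaks up the slides. The test therefore cannot tell an effect of age or genotype from one of the slide. With the scan date as a block 2040 genes differed by genotype and 737 by age.

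A test of the difference between genotypes singled out 6 genes with a difference in rhythm. Of the 100 regroupings, the real one included, 5 gave at least as many, up to 1653. By the rule set beforehand chance is not excluded for this count, but the test cannot decide it. Swapping genotypes at some times can turn a genotype mean difference into a difference in rhythm. The regroupings with 1653, 1621 and 923 calls had 0 genes with a genotype mean difference, and the one with 104 calls had 28. Whether this accounts for all such calls was not traced further. The amplitude in Cre minus floxed livers was -1.53 for Elovl3, -1.47 for Arntl, -0.99 for Spon2, -0.95 for Lgalsl (on a probe with the telomere repeat), -0.81 for A630005I04Rik and -0.61 for Dnmt3b.

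The interaction of age and genotype singled out 2019 genes. Of the 100 regroupings, the real one included, 7 gave as many, up to 5211. By the rule set beforehand chance is not excluded, but here too the test cannot decide. Swapping ages in more pairs of 1 genotype than of the other can turn an age difference into an interaction. The regroupings with 5211, 2314 and 2028 interactions had 0 genes with an age difference. Those with 3003, 2162 and 2080 interactions still had 3753, 2415 and 1504, so this does not describe them all. The fits of the interaction leave out the shared collection, and 812 genes were called with the slide as a block, 147 with the scan date and 4201 with collections as blocks. Among the named genes the genotype difference at 20 minus 10 weeks was 1.03 for Lpl, -0.86 for Gstm2, -1.67 for Cidec, -1.16 for Dio1, -1.06 for Clstn3 and -1.03 for Cry1. It was -0.74 for Cyp3a25. The fit also gave -1.26 for Cyp2e1 and 1.01 for Cyp3a11, which are listed for the test alone and are no measured folds, as Cyp3a11 was saturated in Cy5 on all arrays and Cyp2e1 on 11 of 12 at 10 weeks. The genotypes, with 12 arrays each, were too large as groups for the test of single far samples.

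The first weighed pattern is the 235 genes at least 2-fold higher at 20 weeks. Of their probes 66.8% hold a 6-base window of the telomere repeat, against 4.7% of the other 18731 genes, and over the 20-week arrays a gene of the 157 with the repeat followed the median of the other such genes with a median r of 0.97, where a gene of the 78 without it followed the median of its own set with 0.49, so binding of telomere-derived sequence to these probes is a candidate explanation for most of the pattern. Both 20-week ZT0 arrays, where the profile was highest (3.00 and 3.79), are not its cause alone, since 100% of the 235 genes stayed past the threshold without them. What differed in the 20-week RNA or labelling stays open, age itself included, as the ages were separate collections. The repeat covers 3.6% of the genes higher and 5.6% of those lower in Cre livers, so it does not carry the genotype result.

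The second pattern is the smaller rhythms in Cre livers, where 282 of 290 genes had the smaller amplitude. Choosing genes for their rhythm in floxed livers favours this, but among 290 genes chosen on the floxed arrays of 1 age 64.8% (10 weeks) and 81.7% (20 weeks) had the smaller amplitude in Cre livers at the other age, while genes chosen on Cre arrays gave 45.5 and 56.9%. Loss of the hepatocyte clock gene is the biological explanation the design names, and these values are consistent with it, as a hypothesis found and tested on the same arrays.

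The third pattern is that Cy5 varies and Cy3 does not. Sample RNA in Cy3, as the labels name the dyes, would give Cy3 the larger spread, yet on each of the 6 slides with more than 1 array at least 80.4% of probes varied more in Cy5. Noise in Cy5 would carry no clock, yet 86.4% of the core clock genes (19 of 22) had the larger rhythm statistic in Cy5 on the floxed arrays, as with Arntl (54.3 against 3.37) and Dbp (84.0 against 6.88). A dye statement reversed in the labels, or red and green exchanged in the files, may account for it, and no table here separates these. No biological explanation was tested.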

How the results depend on the processing

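Alternatives added after the data were seen are the scan date as a block, the 10-week arrays with a slide block, the fit without both 20-week ZT0 arrays, the Cy5 filter, the slide block for gene lists, alone and with an estimated correlation, and the fit without telomere-repeat probes; the others were planned. Of 5108 values of named genes under other settings 4528 kept their side of the threshold (60 of them, called in neither fit, with the other sign), 557 fell below it, 22 rose past it and 1 called value reversed. With 1 array left out, 6979 of 7344 kept their side (23 with the other sign), 349 fell below, 16 rose past it and 0 called values reversed. The reversed value is Btg2 at 20 against 10 weeks, 0.47 without telomere-repeat probes, where another probe stands for the gene, and it ran from -0.43 to -0.30 with 1 array left out. Counts for genotype mean, floxed rhythms and age stayed within 1.5 times the main value under all other settings than those below. Called amplitudes in floxed livers that moved by over 1.5 times included, as the mean of all probes, 0.58 for Nr1d1, 0.18 for Per2, 0.84 for Fkbp5, 0.6 for Trib3 and 0.42 for Sox9, and with the scanner's log ratio 3.01 for Ciart and 1.63 for Wee1. Called mean differences that did so included, with the scanner's log ratio, 2.43 for Npas2, -2.43 for Ciart, -1.54 for Nr1d1 and -2.67 for Acot3, as the mean of all probes 2.86 for Ntrk2, -0.86 for Trib3 and -0.36 for Nr1d1, and with slides as blocks 1.51 for Cry1. Unless a reason is given, the cause was not tested.

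Without background subtraction 46 genes were called at ZT4 and 179 at ZT12. The scanner's log ratio and the identical series matrix values gave 11 differences in rhythm, 35 genes at ZT0, 36 at ZT16 and 1220 interactions. Without a filter 1 gene was rhythmic in Cre livers, 13 were called at ZT20 and 9 lists shifted. With age left out, which puts its variation into the error, 154 genes were rhythmic in floxed livers, and 14, 9, 24, 44, 28 and 11 were called from ZT0 to ZT20, 65 at any time. With collections as blocks (correlation 0.293) there were 10 differences in rhythm, 43 genes at ZT0, 45 at ZT4, 185 at ZT12, 136 at ZT16, 320 at any time and 4201 interactions. With slides as blocks (a fixed term, random with correlation 0.222 for age and interactions) there were 1840 genotype differences, 453 floxed rhythms, 1 Cre rhythm, 10 differences in rhythm, 14 genes at ZT0, 13 at ZT20, 99 at any time, 2018 age differences, 812 interactions and 14 shifted lists. With the scan date as a block there were 2040 genotype differences, 651 floxed and 11 Cre rhythms, 82 genes at ZT0, 87 at ZT4, 737 age differences and 147 interactions. Both fixed terms absorb the 10-week Cre array of ZT16, alone on its slide and scan date. That leaves 1 Cre array at ZT16, so no count is given there for either block. Array weights gave 7209 genotype differences, 495 floxed and 108 Cre rhythms, 362 genes at ZT4, 619 at ZT12, 206 at ZT16 and 912 at any time. With 6 times as a factor, 76 genes were rhythmic in floxed livers, 0 differed in rhythm by limma and 1218 had an interaction. The 10-week arrays alone, which are fewer, gave 645 genotype differences, 7 floxed rhythms and 0 differences in rhythm, and with a slide block 1343, 7 and 0. The 20-week arrays alone gave 11 floxed rhythms, 1 Cre rhythm and 0 differences in rhythm. Without both 20-week ZT0 arrays there were 2 differences in rhythm, 3 genes at ZT0 and 5238 interactions. At an adjusted p under 0.01, stricter by construction, 2287 genotype differences, 126 floxed rhythms, 2 differences in rhythm, 3312 age differences, 12 interactions, 6, 13, 26, 38, 17 and 9 genes from ZT0 to ZT20 and 50 at any time remained in count. With an adjusted p under 0.05 and a size of at least 1 the counts were 144, 30, 2 and 271, with 50 at ZT16 and 204 interactions. Camera with an estimated correlation shifted 0 of 32 lists, against 5 with the preset one, and 0 with slides as blocks as well.

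With 1 array left out, the genotype mean gave 3629 to 4952 genes, floxed rhythms 173 to 298, Cre rhythms 0 to 28, differences in rhythm 2 to 10, age 4954 to 6780 and interactions 968 to 4335. By time the ranges were 5 to 1047 at ZT0, 1 to 55 at ZT4, 14 to 89 at ZT8, 29 to 161 at ZT12, 23 to 84 at ZT16, 7 to 31 at ZT20 and 115 to 1171 at any time. There the lone array left at a time is assumed to vary like the others, and 1047 came without floxed replicate 1, 173 without floxed replicate 10, 28 without Cre replicate 5 and 4335 without Cre replicate 7. Interactions were 1336, 968 and 1071 without floxed replicates 2, 4 and 9, and 1189, 1195, 1268, 1296, 1010 and 991 without Cre replicates 3, 5, 6, 10, 11 and 12. Other counts that moved by over 1.5 times were 5 at ZT0 without floxed replicate 7, 9 and 11 without Cre replicates 1 and 7; at ZT4, 2 without floxed replicate 8 and 55, 1, 45 and 45 without Cre replicates 2, 8, 5 and 11; at ZT8, 14, 26, 49 and 49 without floxed replicates 3, 9, 4 and 10 and 14 without Cre replicate 3. At ZT12 they were 35 and 40 without floxed replicates 4 and 10 and 46, 29, 161 and 161 without Cre replicates 4, 10, 5 and 11; at ZT16, 45 without floxed replicate 5 and 45 and 23 without Cre replicates 5 and 11; at ZT20, 7, 11 and 11 without floxed replicates 6, 3 and 9 and 9 and 7 without Cre replicates 6 and 12. At any time they were 1171, 115 and 117 without floxed replicates 1, 4 and 10. Aquantile scaling moves no log ratio by construction. Differences by time within 1 age were not run, as no residual degrees of freedom remain. Signal limits the rest, since between 56.7 and 70.3% of probes were well above background in Cy5, and saturation hides differences of the brightest genes at 10 weeks. Across scalings the all-gene median stayed within 0.02, while the share of the called age differences that were higher at 20 weeks went from 57.5 to 47.7% under the scanner's log ratio.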

Other observations

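Pancreas genes stood high on a single array, the Cre liver of ZT4 at 20 weeks, a pattern noticed in the values and not tested further. Cpb1, a carboxypeptidase of pancreatic juice, had a log2 ratio of 6.59 there against 1.15 on the next highest array, and the elastases Cela3b (5.84 against 0.74), Cela1 (3.76 against 0.61) and Cela2a (3.20 against 0.41) followed. The lipase Cel (3.73 against 1.01), the colipase Clps (3.61 against 1.69), the amylase Amy2 (3.56 against 1.33), Rnase1 (3.17 against 0.09) and Ctrb1 (1.99 against 1.13) were highest on the same array.

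A few genes, picked after their values were seen and not tested, were highest on the floxed array of ZT16 at 10 weeks. They were the metallothioneins Mt1 (2.60 against -0.15 on the next array) and Mt2 (1.90 against -0.95) and Lcn2, an iron-binding acute phase protein (2.58 against 1.15).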
